A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

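Transcript levels in 3 deletion strains of budding yeast were compared with those of a wild type strain on 18 arrays with 2 channels each. The strains lacked DOT4, UBP8 or both genes, and DOT4 is listed under its other name UBP10 below. Per the labels, each array carried total RNA of a null strain in the first or second channel and total RNA of the wild type in the other, from cells grown in YEPD, a rich glucose medium. The labels number 3 sets of arrays for each genotype, and a set holds 2 arrays with the null RNA in opposite channels. They do not say whether the sets came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

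The authors deposited 1 log2 ratio per ORF and array, for 6205 ORFs. The background correction, the normalization, the array design and the spots behind each value are not given in the sources used here, and channel intensities were not used here, so no ORF could be called present or absent. Scale, centring and direction were read from the values. The log2 scale fits a stand-in value of 16.6, the log2 of 1e+05, that occurred 2 times and was treated as missing along with 9 empty values. The columns were not centred as deposited. In the dot4 null the medians were 0.30, 0.17 and 0.30 with the null RNA in channel 2 and -0.02, 0.08 and 0.17 with it in channel 1. In the ubp8 null they were -0.01, 0.26 and 0.07, and 0.08, 0.13 and 0.20, and in the double null -0.18, -0.14 and 0.26, and 0.11, -0.02 and -0.12, in the same order. The labels name the strain in each channel, and not the dye or the order of division. UBP10 and UBP8 were low in the strains lacking them on all 12 arrays of each deletion only if the values run as channel 2 over channel 1, and this direction was used throughout. It rests on these 2 genes, and the design as first written had assumed the opposite order from the labels. The background correction and normalization stay unknown.

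Each array was centred on its median over all ORFs, and its sign was turned where the null RNA was in channel 1, so that all values read null over wild type. The 2 arrays of a set were averaged, which cancels a dye effect of equal size in both orientations, and the 9 set means were the replicates, 3 for each genotype. ORFs with at least 2 set means in each genotype were tested, which left out none. A linear model with a mean for each genotype was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), each genotype was tested against 0, and 4 contrasts compared the genotypes, including the double null minus the sum of the single nulls. P-values were adjusted by Benjamini and Hochberg over the 6205 ORFs within each comparison, with a threshold of 0.05. Errors are the standard error of limma's fit with n = 3 set means unless said otherwise, and the number of arrays limits the precision. The fit estimates a single spread per ORF from the set means of all genotypes. The median SD between set means was 0.041 in the dot4 null, 0.052 in the ubp8 null and 0.064 in the double null. Errors may therefore be too small for the double null and too large for the dot4 null. The wild type RNA enters as the other channel of every array, so its own spread between cultures is not separated.

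Of 46 gene lists fixed before the data were examined, 45 had at least 4 measured members and were tested with limma's camera at a preset correlation of 0.01. The p-values were adjusted over the 45 lists within each comparison. Camera with an estimated correlation and fry, which tests the genes of a list alone, were alternatives. Subtelomeric ORFs had been planned as those within 20 kb of a chromosome end. The deposited table names no genome build, so distances were not used, and the 10 ORFs with the highest systematic numbers on each arm were taken in their place, a choice made after the file was seen. Symbols were taken by locus tag from a RefSeq gene table of the R64 assembly, which matched 5705 of the 6205 ORFs, and the systematic name was kept for the other 500.

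Genes were named by a rule fixed before the data were examined. It took UBP10 and UBP8 in each comparison, the 10 largest increases and decreases past the threshold in each genotype with all set means on the same side of 0, the 5 largest in each direction of each contrast, up to 4 of the largest called members of a gene list, and the measured marker genes of common laboratory strains. Genes outside this rule are said to be so. The 3 genotypes were compared with the same wild type strain, and the labels do not say whether its RNA preparations were shared. Correlations between genotypes were therefore set beside values from 100 simulations of unchanged strains with a shared reference.

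The procedure was tested on simulated data over the 6195 ORFs with all 9 set means, with changes placed in the dot4 null. A dye effect of unequal size in the orientations was not simulated, so the counts that follow do not cover it. Of 50 ORFs changed by 0.1 on the log2 scale 9 were called, of 50 changed by 0.2 there were 45, and all 50 changed by 0.3 were called, with 10 calls among 5975 unchanged ORFs. Alternatives covered no centring, scaling of the arrays to a common spread, each orientation alone, all 18 arrays with a dye term, the set number as a block, filters on missing values, a robust variance estimate, each genotype alone, a 1.5-fold minimum, each set left out in turn, other definitions of subtelomeric ORFs and other list tests. All 18 array columns were used. On a single double null array the strain number in the label was that of the ubp8 null while the genotype named both deletions. It was kept, and the fits were repeated without it.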

Results

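RNA from 3 null strains of Saccharomyces cerevisiae was compared with wild type RNA on 18 arrays, 6 for each genotype. DOT4, now named UBP10 (YNL186W), and UBP8 (YMR223W) encode ubiquitin-specific proteases that remove ubiquitin from histone H2B, and UBP8 is a subunit of the SAGA coactivator complex. The design asked which transcripts depend on each protease, and whether the strain lacking both differs from the sum of the single deletions. All values are log2 ratios of null over wild type, means of 3 set means with the standard error of the limma fit. Their direction was set by the 2 deleted genes, and read in the order in which the labels name the channels every sign would be turned.

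UBP10 was low on every array of the strains lacking it. Values of sets 1 to 3 are given first with the null RNA in channel 2 and then in channel 1. On the 6 dot4 null arrays it read -4.86, -5.10, -4.27, -5.57, -5.29 and -5.24, and on the 6 double null arrays -5.33, -5.58, -4.67, -3.88, -4.23 and -4.49. UBP8 read -2.66, -2.31, -3.11, -3.20, -3.25 and -3.11 on the ubp8 null arrays and -3.79, -3.76, -3.38, -1.49, -2.08 and -3.15 on the double null arrays. The means were -5.06 ± 0.08 for UBP10 in the dot4 null and -4.70 ± 0.08 in the double null, and -2.94 ± 0.09 for UBP8 in both the ubp8 null and the double null. Neither gene was called in the strain that kept it, UBP10 at -0.17 ± 0.08 in the ubp8 null (adjusted p = 0.108) and UBP8 at -0.07 ± 0.09 in the dot4 null (adjusted p = 0.521). The double null array whose label carries the strain number of the ubp8 null read -4.67 for UBP10 and -3.38 for UBP8. FSH2, a neighbour of UBP8, fell in the double null (-0.77 ± 0.03) and in the ubp8 null (-0.55 ± 0.03), where it was the only called gene of the 4 neighbours of the deleted genes and lay outside the naming rule. SWT21, a neighbour of UBP10, rose in the dot4 null (0.22 ± 0.03) and in the double null (0.60 ± 0.03).

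**Figure D1:**
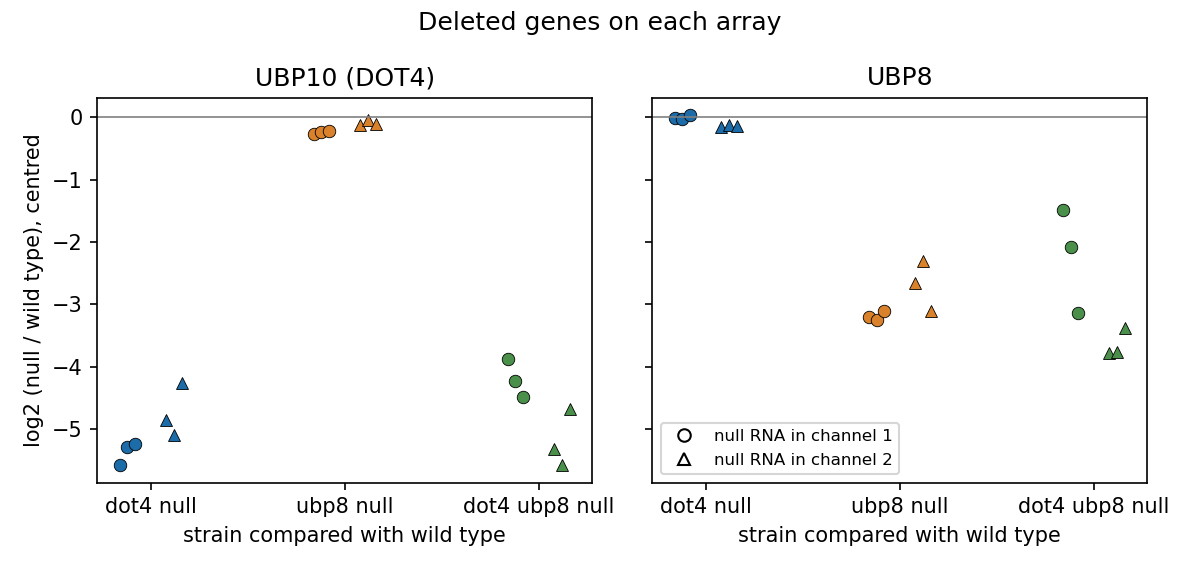
Log2 ratio of null over wild type for UBP10 (left) and UBP8 (right) on each of the 18 arrays, circles with the null RNA in channel 1 and triangles with it in channel 2. UBP10 lies between -5.58 and -3.88 in the strains lacking it, UBP8 lies between -3.79 and -1.49 in its own, and both lie near 0 in the strain that kept them.

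In the dot4 null, URA3, a gene of uracil synthesis, rose 11.4-fold (3.51 ± 0.09) and ADH4, an alcohol dehydrogenase gene near the left end of chromosome VII, rose 10.2-fold (3.36 ± 0.07). The next largest increases were near 2-fold and included the seripauperin genes PAU5 (1.14 ± 0.04) and PAU19 (1.04 ± 0.04) and the helicase genes YRF1-6 (1.04 ± 0.04) and YRF1-2 (1.03 ± 0.03) of the telomeric Y' elements. Others were SER3 of serine synthesis (1.12 ± 0.04), the chaperone gene SSA4 (1.07 ± 0.05), and DDI2 (1.05 ± 0.06) and DDI3 (1.10 ± 0.05), nearly identical genes that the arrays may not tell apart. Besides UBP10, the phosphate transporter gene PHO89 fell most, 4.54-fold (-2.18 ± 0.06), and HIS3 of histidine synthesis fell 3.63-fold (-1.86 ± 0.05), with YOR203W, the ORF numbered next to HIS3, at -1.88 ± 0.06. Decreases were also found for the acid phosphatase genes PHO12 (-1.48 ± 0.05) and PHO11 (-1.38 ± 0.04), which are close copies, the secreted glycoprotein gene YGP1 (-1.36 ± 0.05), the dehydrogenase gene YNL134C (-1.19 ± 0.05), SPL2 (-1.12 ± 0.04) and YMR173W-A (-1.08 ± 0.04), an ORF that overlaps DDR48 (-0.90 ± 0.04).

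Of 6205 ORFs, 1857 were higher and 1993 lower in the dot4 null at an adjusted p under 0.05 in limma, and 114 and 59 of these changed at least 1.5-fold. Without centring the split was 1804 higher and 563 lower. The median standard error was 0.034 and the smallest called change 0.06. Of the called ORFs 80.5% had the same direction in both orientations, and of the 173 past 1.5-fold 168 were called the same way in each.

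Genes near chromosome ends rose in the dot4 null. Of 328 subtelomeric ORFs, 197 rose and 52 fell (200 and 54 adjusted over the list alone), and 20.4% were at least 1.5-fold higher, against 0.80% of all other ORFs. The median of these ORFs lay 0.18 ± 0.01 (SD, n = 3 sets) above that of other ORFs (camera, adjusted p = 4.01e-10, and adjusted p = 0.273 with an estimated correlation). Without the genes listed for the seripauperin, COS, Y' helicase and other repeated families, which left 283 ORFs, the shift was 0.16 ± 0.01 (SD, n = 3). The median of the 5 ORFs nearest to each end, averaged over the set medians, was 0.31, that of the next 5 was 0.07 and that of the next 5 was 0.02. Of 23 seripauperin genes, 21 rose, 20 of them at least 1.5-fold, with a median of 0.84 (adjusted p = 1.6e-14, and adjusted p = 0.273 with an estimated correlation). All 7 Y' helicase genes rose, with a median of 1.01 (adjusted p = 2.41e-07, and 0.331 as the adjusted p with an estimated correlation). The members of both families share sequence and may not be told apart on these arrays. At the silent mating loci HMRA2 (0.13 ± 0.03), HMRA1 (0.11 ± 0.04) and HMLALPHA2 (0.10 ± 0.03) rose slightly, calls that ended in a single orientation and, for HMRA1 and HMLALPHA2, without set 2, and the list of 4 was not called (adjusted p = 0.257).

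Ribosome biogenesis genes rose in the dot4 null, 77 of 84 with none lower (79 adjusted over the list alone) and a median of 0.29 (adjusted p = 4.39e-19, and adjusted p = 0.348 with an estimated correlation). The helicase gene FAL1 (0.75 ± 0.04) and the processing factors NOP15 (0.58 ± 0.05) and UTP7 (0.57 ± 0.03) led the list. Ribosomal protein genes fell, 133 of 138 with 2 higher and a median of -0.32 (adjusted p = 1.16e-22, and adjusted p = 0.348 with an estimated correlation). The largest decreases among them were in RPL22B (-0.85 ± 0.03) and RPS22B (-0.84 ± 0.06). Phosphate genes fell, 14 of 16 with a median of -0.57 (adjusted p = 2.58e-07, and adjusted p = 0.273 with an estimated correlation). Glycolysis genes fell, 16 of 18 with 1 higher, with PGK1 at -0.66 ± 0.04 (adjusted p = 1.29e-05, and adjusted p = 0.348 with an estimated correlation). Respiratory chain genes fell, 26 of 36 with none higher, among them COX4 (-0.48 ± 0.06) and ATP1 (-0.41 ± 0.05). The list had adjusted p = 0.000257, and adjusted p = 0.552 with an estimated correlation. Targets of the unfolded protein response fell, 13 of 15 with KAR2 at -0.34 ± 0.03 (adjusted p = 0.000896, and adjusted p = 0.315 with an estimated correlation). Thiamine genes rose, 13 of 18 with THI5 at 0.83 ± 0.06 (adjusted p = 0.00428, and adjusted p = 0.348 with an estimated correlation), and so did 10 of 19 pheromone-induced genes, with AGA1 at 0.72 ± 0.05 and PRM1 at 0.59 ± 0.03 (adjusted p = 0.0067, and adjusted p = 0.348 with an estimated correlation). Counts adjusted over the list alone were the same for these last 7 lists. In all, 17 of 45 lists passed in the dot4 null, and with an estimated correlation none did in any genotype, the lowest adjusted p being 0.273, 0.408 and 0.192 in the dot4, ubp8 and double null. At an unadjusted p under 0.05 with an estimated correlation 5, 4 and 8 lists passed, and with fry 39, 31 and 36 at an adjusted one. Of 9 genes used as strain markers, 3 rose and 5 fell (3 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.269). Past 1.5-fold, ADE2 rose (0.79 ± 0.05) and LEU2 fell (-0.73 ± 0.03) besides URA3 and HIS3. The list of 14 H2B ubiquitination genes, which holds UBP10, had a median of 0.09 and a mean of -0.28, camera and fry pointed in opposite directions, and camera did not call it (adjusted p = 0.206).

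Single orientations differed in the dot4 null. With the null RNA in channel 1 and in channel 2 the median was -0.63 and -0.04 for ribosomal proteins, -0.71 and -0.09 for glycolysis and -0.27 and -0.08 for the respiratory chain, and the calls of these lists and of the thiamine and pheromone lists ended with channel 2 alone. The biogenesis (0.22 and 0.35), seripauperin (0.84 and 0.83), Y' helicase (0.75 and 1.28) and phosphate (-0.72 and -0.43) lists passed in each.

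In the ubp8 null the changes were smaller. The largest increases were near 2-fold, in the stress gene HSP31 (1.02 ± 0.06), YNL134C (0.96 ± 0.05) and the reductase gene GRE2 (0.94 ± 0.04), followed by YOL150C (0.83 ± 0.03), YJL218W (0.82 ± 0.03), the mannoprotein gene TIR1 (0.78 ± 0.05), the carnitine acetyltransferase gene YAT1 (0.76 ± 0.06), YFR035C (0.75 ± 0.05), ARO10 (0.74 ± 0.06) and FMP48 (0.70 ± 0.10). Besides UBP8, PHO89 fell 2.68-fold (-1.42 ± 0.06), the transcription factor gene RDS1 fell 1.99-fold and ADE2 of purine synthesis fell 1.95-fold (-0.96 ± 0.05). Further decreases were found in the phosphatase genes PHO5 (-0.80 ± 0.05) and PHO3 (-0.76 ± 0.04), the hexose transporter gene HXT2 (-0.73 ± 0.03), ADE17 (-0.71 ± 0.05) and the Ty element ORF YBL005W-A (-0.76 ± 0.07).

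There were 1862 ORFs higher and 1778 lower in the ubp8 null, of which 26 and 21 changed at least 1.5-fold, and without centring 778 were higher and 804 lower. Without set 1 there were 27 ORFs past 1.5-fold in place of 47, and scaling the arrays to a common spread or channel 1 alone gave more, with counts given below. Of the called ORFs 90.2% had the same direction in both orientations, and 39 of the 47 were called the same way in each.

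Ribosome biogenesis genes fell in the ubp8 null, 79 of 84 with none higher (80 adjusted over the list alone) and a median of -0.24 (adjusted p = 4.48e-19, and adjusted p = 0.408 with an estimated correlation). They included RPA190 (-0.51 ± 0.03) and RPA135 (-0.50 ± 0.05), the large subunits of RNA polymerase I, and NOG1 (-0.46 ± 0.03). Stress-induced genes rose, 36 of 47 with 3 lower (36 and 4 adjusted over the list alone), with HSP42 at 0.67 ± 0.11, HSP26 at 0.56 ± 0.06 and SOL4 at 0.55 ± 0.06. Tested as a list they had adjusted p = 9.52e-07, and adjusted p = 0.411 with an estimated correlation. Purine genes fell, 11 of 15 with none higher and ADE13 at -0.52 ± 0.04, on either adjustment (adjusted p = 2.06e-05, and adjusted p = 0.408 with an estimated correlation). Phosphate genes fell, 14 of 16 with a median of -0.28 and the same 14 adjusted over the list alone (adjusted p = 7.78e-06, and adjusted p = 0.408 with an estimated correlation). Sporulation genes rose, 24 of 31 with 2 lower (25 and 2 adjusted over the list alone), among them the meiotic genes HOP1 (0.50 ± 0.04) and DMC1 (0.49 ± 0.03). The list had adjusted p = 2.06e-05, and adjusted p = 0.408 with an estimated correlation. Seripauperin genes rose, 20 of 23 on either adjustment with none past 1.5-fold, PAU5 at 0.46 ± 0.04 and PAU19 at 0.42 ± 0.04 (adjusted p = 9.52e-07, and adjusted p = 0.408 with an estimated correlation). Thiamine genes rose, 14 of 18 with THI5 at 0.62 ± 0.06 and 14 adjusted over the list alone (adjusted p = 0.000326, and adjusted p = 0.408 with an estimated correlation). DNA damage genes rose, 8 of 12 with 2 lower (9 and 2 adjusted over the list alone), among them MAG1 (0.43 ± 0.03) and RNR3 (0.39 ± 0.03). Camera gave adjusted p = 0.00725, and adjusted p = 0.408 with an estimated correlation. Subtelomeric ORFs rose, 160 of 328 with 51 lower (162 and 52 adjusted over the list alone) and a shift of the median of 0.11 ± 0.03 (SD, n = 3), with 1.52% of them at least 1.5-fold higher. The list had adjusted p = 0.000462, and adjusted p = 0.408 with an estimated correlation. Of 19 SAGA subunit genes 8 fell and 1 rose (8 fell and 0 rose adjusted over the list alone), the 8 including UBP8 itself and TRA1 (-0.23 ± 0.03). As a group they had adjusted p = 0.0445, and adjusted p = 0.408 with an estimated correlation. UBP8, whose fall the deletion itself gives, was part of that test, which was not repeated without it. The median of the list was -0.07 and its mean -0.23. In all, 21 of 45 lists passed.

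The direction of 4 called lists turned between the orientations in the ubp8 null. With the null RNA in channel 1 and in channel 2 the median was -0.30 and 0.14 for ribosomal proteins (-0.07 overall), -0.21 and 0.55 for glycolysis (0.23), -0.07 and 0.44 for histone genes (0.18) and -0.02 and 0.30 for Y' helicases (0.17). The sporulation and subtelomeric calls ended with channel 2 alone (medians of 0.03 and 0.05), and the SAGA call ended in each orientation.

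The double null carried the largest number of ORFs past 1.5-fold. BPH1, whose product resembles the Chediak-Higashi protein, rose 5.33-fold (2.41 ± 0.08), the stress gene HSP12 rose 4.01-fold, ADH4 rose 3.71-fold (1.89 ± 0.07) and the thiamine synthesis gene THI4 rose 3.67-fold (1.87 ± 0.09). They were followed by FMP48 (1.66 ± 0.10), YAT1 (1.64 ± 0.06), THI5 (1.62 ± 0.06), the chaperone gene HSP26 (1.60 ± 0.06), PAU19 (1.48 ± 0.04) and THI12 (1.48 ± 0.04), of which THI5 and THI12 are close copies. Besides the deleted genes, the phosphate genes PHO89 (-2.90 ± 0.06), PHO12 (-2.22 ± 0.05), PHO11 (-2.20 ± 0.04) and SPL2 (-1.67 ± 0.04) fell most, PHO89 by 7.47-fold. The other large decreases were all in Ty element ORFs, repeated sequences that arrays do not separate, namely YBL005W-A (-1.67 ± 0.07), YMR046C (-1.57 ± 0.08), YBR012W-A (-1.44 ± 0.06) and YJR026W (-1.44 ± 0.07). The median of 21 Ty ORFs, a list made after the data were seen, was -1.79 with channel 1 and -0.18 with channel 2 in this strain. URA3 was at 1.25 ± 0.09, HIS3 at -0.37 ± 0.05 and ADE2 at 0.17 ± 0.05, a call that ended without centring (adjusted p = 0.0588).

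There were 2189 ORFs higher and 2186 lower in the double null, and 351 and 121 of them changed at least 1.5-fold. Of the called ORFs 94.7% had the same direction in both orientations, and 442 of the 472 past 1.5-fold were called the same way in each.

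Subtelomeric ORFs rose in the double null, 236 of 328 with 42 lower (237 and 43 adjusted over the list alone), and 25.9% were at least 1.5-fold higher, against 4.53% of other ORFs. The shift of the median was 0.33 ± 0.04 (SD, n = 3), with adjusted p = 5.44e-13, and adjusted p = 0.192 with an estimated correlation. Averaged over the set medians, the 5 ORFs nearest to each end lay at 0.40, the next 5 at 0.20 and the next 5 at 0.08, and the median of the gene means of the first 5 was 0.45. Seripauperin genes rose, 20 of 23 on either adjustment with a median of 1.12 and PAU5 at 1.46 ± 0.04 (adjusted p = 1.01e-10, and adjusted p = 0.214 with an estimated correlation). Y' helicase genes rose, 7 of 7 with a median of 0.57 and YRF1-2 at 0.66 ± 0.03 (adjusted p = 0.0002, and adjusted p = 0.308 with an estimated correlation). Sporulation genes rose, 29 of 31 with 2 lower and 13 at least 1.5-fold higher, among them GAS4 (1.14 ± 0.07), SPS1 (0.94 ± 0.06) and REC8 (0.93 ± 0.08). The list had adjusted p = 6.75e-08, and adjusted p = 0.192 with an estimated correlation. Stress-induced genes rose, 36 of 47 with 23 at least 1.5-fold higher and SOL4 at 1.24 ± 0.06 (adjusted p = 6.82e-08, and adjusted p = 0.308 with an estimated correlation). Phosphate genes fell, 14 of 16 with a median of -1.03 (adjusted p = 1.04e-06, and adjusted p = 0.214 with an estimated correlation), and purine genes fell, 12 of 15 with ADE17 at -1.28 ± 0.05 (adjusted p = 0.000362, and adjusted p = 0.308 with an estimated correlation). Thiamine genes rose, 15 of 18 with a median of 0.66 (adjusted p = 5.5e-05, and adjusted p = 0.214 with an estimated correlation). DNA damage genes rose, 11 of 12 with the ribonucleotide reductase gene RNR3 at 1.02 ± 0.03 and the repair gene RAD54 at 0.68 ± 0.03 (adjusted p = 7.25e-05, and adjusted p = 0.192 with an estimated correlation). Hexose transporter genes rose, 15 of 17 with the close copies HXT12 (0.93 ± 0.03) and HXT9 (0.88 ± 0.04). Camera gave adjusted p = 0.000291, and adjusted p = 0.214 with an estimated correlation. Histone genes rose, 9 of 10 with the H4 genes HHF1 and HHF2 both at 0.71 ± 0.03 (adjusted p = 0.000356, and adjusted p = 0.308 with an estimated correlation). Counts adjusted over the list alone were the same for these last 9 lists. Ribosomal protein genes fell, 126 of 138 (129 adjusted over the list alone) with RPL22B at -1.12 ± 0.03 and RPS22B at -0.96 ± 0.06 (adjusted p = 1.55e-19, and adjusted p = 0.308 with an estimated correlation). Ribosome biogenesis genes split, 20 higher and 30 lower (20 and 29 adjusted over the list alone), and the list was not called (adjusted p = 0.659). In all, 24 of 45 lists passed, and none of them turned in sign between the orientations, although the ribosomal protein median was -0.61 and -0.15 and the histone median 0.14 and 0.81 with the null RNA in channel 1 and channel 2.

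**Figure D2:**
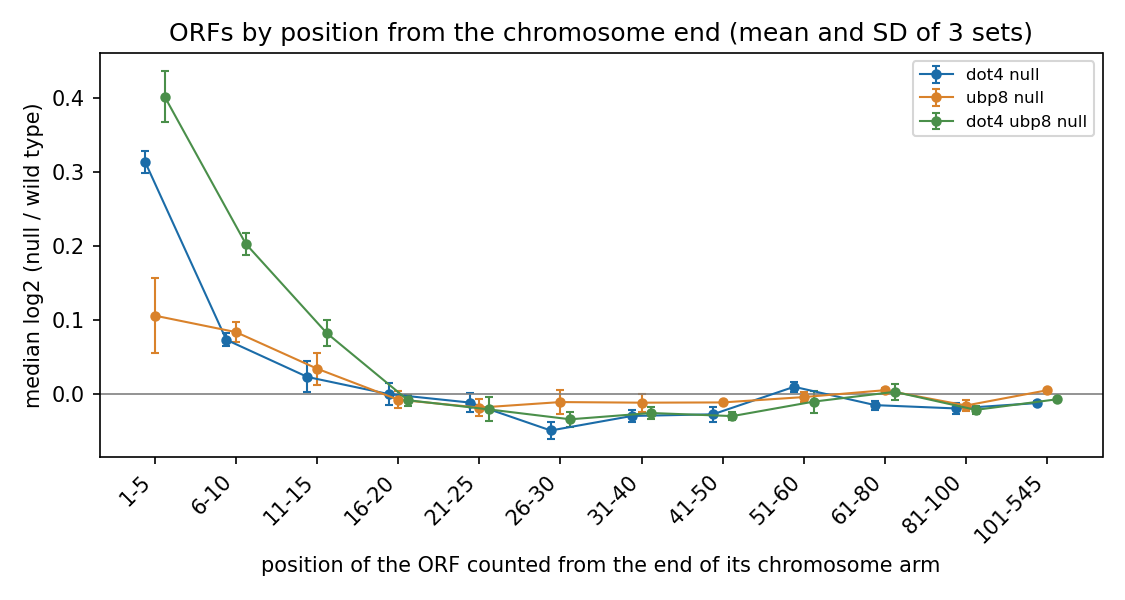
Median log2 ratio of null over wild type of ORFs grouped by their position from the end of the chromosome arm, counted in ORFs by systematic number, for each strain (points, mean of 3 sets, and bars, SD). The first 5 ORFs lie at 0.31 in the dot4 null, 0.11 in the ubp8 null and 0.40 in the double null, and from position 16 on all 3 strains lie within 0.05 of 0.

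The strains were then compared with each other, and the camera tests of these contrasts were not repeated with a single orientation. Between the dot4 null and the ubp8 null, URA3 (3.92 ± 0.14), ADH4 (3.42 ± 0.11), ADE2 (1.76 ± 0.06) and the zinc transporter gene ZRT1 (1.55 ± 0.05) were higher in the dot4 null, besides UBP8 (2.87 ± 0.13). YNL134C (-2.15 ± 0.07), HIS3 (-1.51 ± 0.06), YMR173W-A (-1.41 ± 0.05) and YLR232W (-1.37 ± 0.08) were lower there, besides UBP10 (-4.89 ± 0.12). All 84 ribosome biogenesis genes were higher in the dot4 null than in the ubp8 null, with a median difference of 0.54 (adjusted p = 4.95e-29, and adjusted p = 0.411 with an estimated correlation). Glycolysis genes were lower, 16 of 18 with a median of -0.53 (adjusted p = 5.36e-06, and adjusted p = 0.411 with an estimated correlation), and so were 28 of 47 stress-induced genes with 5 higher and a median of -0.26 (adjusted p = 4.58e-05, and adjusted p = 0.411 with an estimated correlation). Each of these counts was the same adjusted over the list alone. A total of 1731 ORFs were higher and 1872 lower, and 1432 and 481 without centring.

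Against the dot4 null, the double null was higher in BPH1 (1.75 ± 0.11), YAT1 (1.54 ± 0.09), BNA5 of NAD synthesis (1.52 ± 0.06), YLR232W (1.51 ± 0.08), an ORF next to BNA5 by number, and HIS3 (1.49 ± 0.06). It was lower in URA3 (-2.26 ± 0.12), ADH4 (-1.46 ± 0.11) and ADE17 (-0.90 ± 0.07), besides UBP8 (-2.87 ± 0.13), and UBP10 was at 0.36 ± 0.12 (adjusted p = 0.0222), a call that ended without set 1 or 2 of the dot4 null or set 1 or 3 of the double null and turned to -0.45 with channel 2 alone. UBP10 is deleted in both strains, so its value cannot be read as a difference in transcript level. Ribosome biogenesis genes were lower, 75 of 84 with a median of -0.31 (77 adjusted over the list alone) (adjusted p = 2.7e-16, and adjusted p = 0.314 with an estimated correlation). Stress-induced genes were higher, 39 of 47 with a median of 0.59 and 39 adjusted over the list alone (adjusted p = 1.28e-13, and adjusted p = 0.258 with an estimated correlation). Respiratory chain genes were higher, 30 of 36 with a median of 0.29 (32 adjusted over the list alone) (adjusted p = 1.14e-07, and adjusted p = 0.424 with an estimated correlation). The 7 Y' helicase genes were all lower than in the dot4 null, with a median of -0.43 and 7 adjusted over the list alone (adjusted p = 0.00033, and adjusted p = 0.313 with an estimated correlation). There were 1800 ORFs higher and 1814 lower, and 664 and 1318 without centring.

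Against the ubp8 null, the double null was higher in BPH1 (2.60 ± 0.11), ADH4 (1.96 ± 0.11), URA3 (1.65 ± 0.14), HSP12 (1.65 ± 0.07) and the cell wall iron gene FIT3 (1.41 ± 0.19). It was lower in PHO12 (-1.66 ± 0.07), PHO11 (-1.56 ± 0.06), PHO89 (-1.48 ± 0.08) and SPL2 (-1.44 ± 0.05), besides UBP10 (-4.53 ± 0.12), and UBP8 did not differ past the threshold (adjusted p = 0.987). Ribosomal protein genes were lower, 123 of 138 with a median of -0.31 (125 adjusted over the list alone) (adjusted p = 5.74e-26, and adjusted p = 0.317 with an estimated correlation). Ribosome biogenesis genes were higher, 66 of 84 with a median of 0.24 (71 adjusted over the list alone) (adjusted p = 3e-15, and adjusted p = 0.36 with an estimated correlation). Seripauperin genes were higher, 20 of 23 with a median of 0.89 (20 and 1 lower adjusted over the list alone) (adjusted p = 3.3e-15, and adjusted p = 0.15 with an estimated correlation). Phosphate genes were lower, 14 of 16 with a median of -0.58 and 14 adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.15 with an estimated correlation). A total of 1438 ORFs were higher and 1300 lower, and 616 and 319 without centring.

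**Figure D3:**
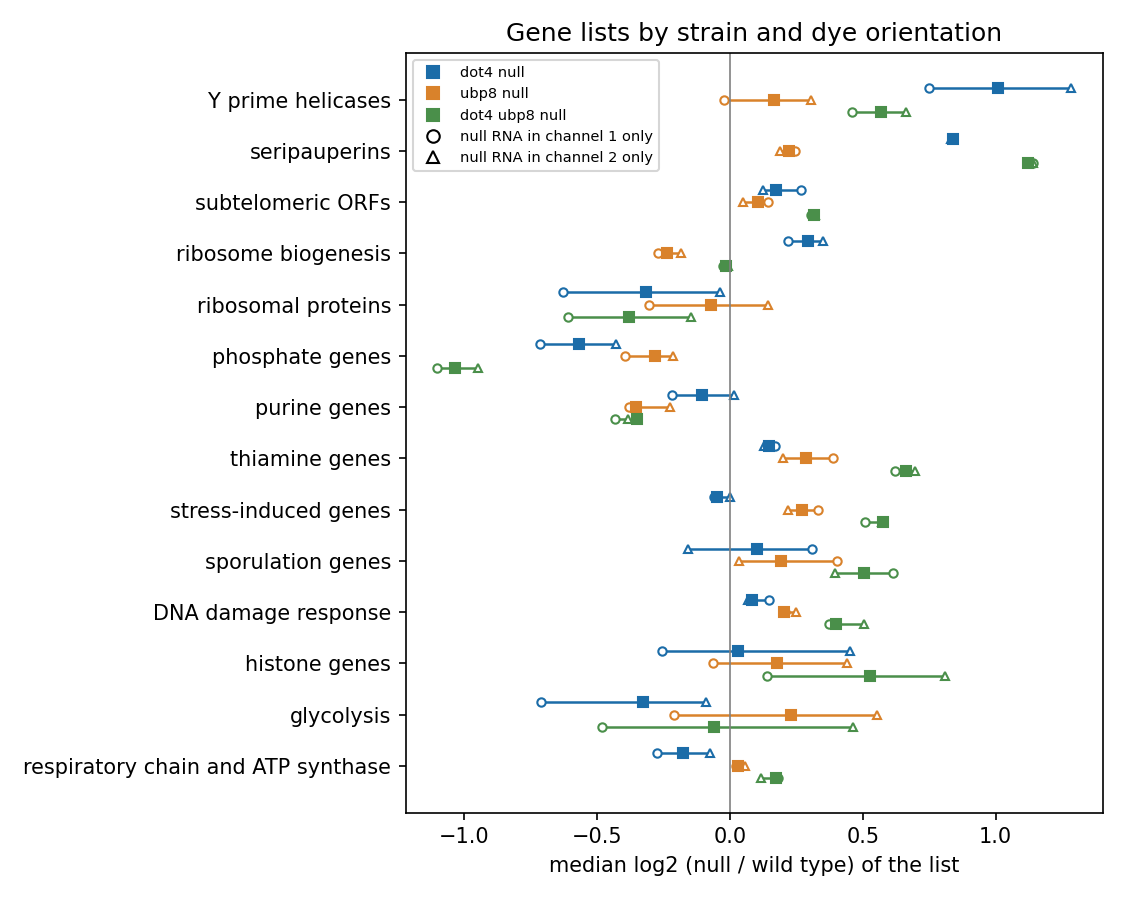
Median log2 ratio of null over wild type of 14 gene lists in the 3 strains (squares, all arrays), and with the arrays of a single orientation (circles with the null RNA in channel 1, triangles in channel 2). Seripauperin medians lie at 0.84, 0.22 and 1.12 in the dot4, ubp8 and double null over all arrays and within 0.05 of these in each orientation, whereas ribosomal protein, glycolysis and histone medians move with it. They turn in sign between the orientations in the ubp8 null, as do histone, sporulation and purine medians in the dot4 null, glycolysis in the double null and Y' helicases in the ubp8 null.

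The double null was last set against the sum of the single nulls. BPH1 (1.93 ± 0.14), HIS3 (1.83 ± 0.08), YOR203W (1.82 ± 0.10), the hexokinase gene HXK1 (1.35 ± 0.06) and BNA5 (1.18 ± 0.08) lay above the sum. URA3 (-1.85 ± 0.16), ADH4 (-1.40 ± 0.13), YFL065C (-0.71 ± 0.06), HPF1 (-0.71 ± 0.08) and YIR042C (-0.70 ± 0.06) lay below it. The ADH4 call ended with channel 2 alone (-0.72, adjusted p = 0.0529). UBP10 was at 0.53 ± 0.14 (adjusted p = 0.0278), a call that ended without any of 6 sets and turned to -0.36 with channel 2 alone, and UBP8 at 0.07 ± 0.16 (adjusted p = 0.796). Both genes are deleted in the double null and each in a single null, so these values cannot be read as transcript levels that depart from the sum. Respiratory chain genes lay above the sum, 23 of 36 with none below and a median of 0.26 (32 adjusted over the list alone) (adjusted p = 5.79e-11, and adjusted p = 0.46 with an estimated correlation). Their medians with channel 1 and channel 2 were -0.27 and -0.08 in the dot4 null, 0.02 and 0.06 in the ubp8 null and 0.18 and 0.11 in the double null. Stress-induced genes lay above it, 28 of 47 with a median of 0.36 (29 adjusted over the list alone) (adjusted p = 1.85e-10, and adjusted p = 0.436 with an estimated correlation). The 7 Y' helicase genes lay below it, with a median of -0.60 and 7 adjusted over the list alone (adjusted p = 8.01e-10, and adjusted p = 0.436 with an estimated correlation). With channel 1 and channel 2 their medians were 0.75 and 1.28 in the dot4 null, -0.02 and 0.30 in the ubp8 null and 0.46 and 0.66 in the double null. The size of the departure may therefore differ between the orientations, which was not tested. Neither the phosphate genes (adjusted p = 0.95) nor the seripauperin genes (adjusted p = 0.943) differed from the sum past the threshold. In total 739 ORFs lay above and 522 below, and 105 and 122 without centring. Without set 2 or 3 of the dot4 null or set 2 of the ubp8 null the 1261 calls fell to 803, 730 and 756, and channel 2 alone gave 2107.

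Across genes, which are not independent replicates, log2 ratios of the dot4 null and the ubp8 null correlated at r = 0.13 (Pearson) and 0.08 (Spearman), those of the dot4 null and the double null at 0.58 and 0.48, and those of the ubp8 null and the double null at 0.72 and 0.72. Unchanged strains with a shared wild type gave r = 0.49 to 0.50 in simulation, but a covariance of 0.001, against 0.0063, 0.0493 and 0.046 observed in the 3 pairs. Pairs of different sets gave mean r values of 0.12, 0.55 and 0.67. The simulated wild type was drawn anew for each set from the spread between sets. A deviation of a wild type RNA common to all sets would be missing from that spread. Neither the simulated covariance nor the pairs of different sets can exclude such a deviation. Of ORFs at least 1.5-fold higher, the double null shared 74 with the dot4 null where 6.45 would be shared by independent lists, and 23 with the ubp8 null against 1.47. Of ORFs at least 1.5-fold lower it shared 35 against 1.15 and 17 against 0.41, and part of these excesses may come from wild type RNA, if the genotypes shared it. Each of these counts of lower ORFs also holds the gene deleted in both strains compared. The single nulls shared 5 higher ORFs against 0.48 and 14 lower ORFs against 0.2. The double null against the sum of the single nulls gave r = 0.84, with fitted slopes of 0.67 on the dot4 null (0.60 to 0.71 over sets) and 1.18 on the ubp8 null (0.97 to 1.22 over sets). UBP10 and UBP8, which the deletions lower on both sides, were part of this r and these slopes, which were not computed without them.

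Chromosome medians lay close to 0 in each strain. The farthest in the double null was chromosome VI at 0.11 ± 0.02 (SD, n = 3 sets), or 0.09 without its subtelomeric ORFs, and in the ubp8 null it was also chromosome VI, at 0.05 ± 0.01. In the dot4 null it was chromosome X at -0.03 ± 0.00.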

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

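The counts over other splits of the set means and the count over chromosome arms were planned before their results were seen, and the other tests of this part were chosen afterwards. Dixon's test was run on the 6 arrays behind each of 62 values of named genes, and 4 had an array set apart from the other 5. YFR035C read 0.39 in the ubp8 null on the set 3 array with the null RNA in channel 2, against 0.75 to 0.91 on the others. RDS1 read -0.81 in the ubp8 null in set 1 with channel 1, against -1.08 to -0.99, and PHO5 read -0.58 there in set 3 with channel 2, against -0.90 to -0.79. PHO11 read -2.41 in the double null in set 3 with channel 1, against -2.20 to -2.10. About 1 in 20 groups of 6 values from a single normal distribution is set apart in this way. The 6 arrays pooled both orientations, which differed by ORF, so that rate may not apply to them.

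Tests of the difference between genotypes found 3603 ORFs that differed between the dot4 null and the ubp8 null, 3614 between the double null and the dot4 null, and 2738 between the double null and the ubp8 null. Ribosome biogenesis genes (median difference 0.54), glycolysis genes (-0.53), ADE2 (1.76) and YNL134C (-2.15) differed between the dot4 null and the ubp8 null, and respiratory chain genes (0.29) between the double null and the dot4 null. ADE2 and YNL134C were the genes past 1.5-fold in opposite directions in the single nulls.

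Turning the signs of the set means gave as many calls in 1 of the 4 splits, the real one, in each of the dot4 null (3850, highest other 0), the ubp8 null (3640, highest other 0) and the double null (4375, highest other 0). Exchanging set means between genotypes gave as many calls in 1 of the 10 splits, again the real one, for 3603, 3614 and 2738 ORFs in the order above, with 0 as the highest other in each. These splits are too few for a share under 0.05. For the departure from the sum of the single nulls 4 of 100 drawn splits, the real one included, gave as many as the 1261 ORFs called, a share under 0.05. Mixing strains that differ widens the spread within a group, which lowers the calls whether or not the deletions add up. The share therefore does not test additivity. The highest other split called 3201, which points to a structure of the samples. Each of the 3 other splits with as many calls was among the 10 that kept the sets of 1 genotype together, and the 89 splits that kept none together called at most 500.

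The rise of subtelomeric ORFs in the dot4 null was weighed first. Cross-hybridisation within the listed repeated families was argued against as the whole cause, since the shift without them was 0.16 ± 0.01 (SD, n = 3 sets). Repeated ORFs outside those lists would have stayed among the 283 ORFs left, so cross-hybridisation among them stays open. Dye bias was argued against by the smaller of the shifts in the 2 orientations, 0.14 ± 0.01 (SD, n = 3). A few engineered chromosome ends were argued against by the 28 of 32 arms that lay above other genes (exact binomial test, p = 1.93e-05). The arm medians kept the repeated families, whose members may not be told apart on these arrays. The arms may therefore not be independent and the p-value may be too small, and the count was not repeated without these families. A loss of silencing with DOT4 remains a hypothesis, and a difference between the strains other than the deletion stays open with 1 strain per genotype.

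URA3 and ADH4 rose far more than other genes in the dot4 null, and the changes of ADE2 and HIS3 there and of BPH1 in the double null were weighed with them. For a change in copy number of the surrounding segments, 20 neighbouring ORFs pooled over all loci had a median of -0.0419 in the direction of the gene (interquartile range 0.23). The pool would hide a change at a single locus. By locus, neighbours lay from -0.0008 to 0.21 at URA3, -0.11 to 0.14 at ADE2, -0.06 to 0.08 at HIS3 and -0.36 to -0.15 at BPH1. These values argue against a change of the whole segment there. Beside ADH4, ZRT1 rose and MNT2 fell (-0.56), so a change at that locus stays open. Of 10 zinc regulon genes 3 were higher in the dot4 null, all at least 1.5-fold, and 1 was lower. Camera did not call that list (adjusted p = 0.235). Against the ubp8 null 6 were higher and 0 lower (camera, adjusted p = 0.0138, and adjusted p = 0.411 with an estimated correlation). Nearby ORFs that did move with their gene were ZRT1 beside ADH4 (0.97) and YOR203W, numbered next to HIS3 and not among the 20 (-1.88), so a change limited to such a pair stays open, and 3 neighbours of URA3 rose by only 0.18 to 0.21. A URA3 marker that came with the deletion of DOT4 cannot be told apart from other causes. URA3 differed between the double null and the dot4 null by -2.26 ± 0.12, but the labels give no markers and each strain may carry its own, and no biological explanation was tested.

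Ribosome biogenesis genes rose while ribosomal protein genes fell in the dot4 null. A difference in growth rate alone was taken to move both lists the same way. Between the dot4 null and the ubp8 null it was argued against by the differences of the 2 lists. These parted by at least 0.73 ± 0.11 (SD, n = 3 sets each) in each orientation. Against wild type the balanced medians had opposite signs, but the fall of the ribosomal protein genes may come from a dye effect, as given below. A difference in growth rate from wild type therefore stays open. Dye bias was argued against for the biogenesis genes, whose smaller median over the orientations was 0.22 ± 0.05 (SD, n = 3). For the ribosomal protein genes a dye effect of equal size in both orientations was argued against by their balanced median of -0.32 ± 0.03 (SD, n = 3). Their difference from the ubp8 null was -0.31 ± 0.05 with channel 1 and -0.19 ± 0.06 with channel 2 (SD, n = 3 sets each). That places the dot4 null below the ubp8 null in each orientation. It cannot decide on a dye effect of unequal size shared by arrays of the same orientation, since the ubp8 null is itself a mutant. With channel 2 alone the median was -0.04 in the dot4 null and 0.14 in the ubp8 null, so such an effect stays open for the fall against wild type. An effect of DOT4 on these genes remains a hypothesis, and a difference between the strains other than the deletion stays open.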

How the results depend on the processing

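Of the settings below, those on the direction of the ratio, on the 1.5-fold counts by orientation, scaling or set, on the number of ORFs per arm and on chromosome medians were chosen after the data were seen. Every direction rests on the 2 deleted genes. In the order in which the labels name the channels UBP10 would be at 5.06 in the dot4 null and 4.70 in the double null, and UBP8 at 2.94 in both the ubp8 null and the double null. Without centring the called ORFs numbered 2367 in the dot4 null and 1582 in the ubp8 null, 1913, 1982 and 935 in the contrasts of dot4 with ubp8, double with dot4 and double with ubp8, and 227 beyond additivity. With each genotype fitted alone the dot4 null had more calls (4194) than the double null (4005), and the ubp8 null had 3472. A 1.5-fold minimum left 173, 47, 472, 322, 296, 175 and 81 in the order dot4, ubp8, double, the same 3 contrasts and non-additive. With channel 1 alone the 1.5-fold counts were 395 in the dot4 null and 177 in the ubp8 null, and with channel 2 alone 265 in the dot4 null. Channel 2 alone also gave 2287 called ORFs in the ubp8 null and 2107 beyond additivity, a subtelomeric shift of 0.0518 in the ubp8 null that was no longer called (adjusted p = 0.0622), and UBP10 at -0.45 in the double null against the dot4 null and at -0.36 against the sum of the single nulls. Scaling arrays to a common spread gave 89 ORFs past 1.5-fold in the ubp8 null. Camera with an estimated correlation called 0 lists in the dot4 null, 0 in the ubp8 null and 0 in the double null, while fry called 39 lists in the dot4 null. The subtelomeric shifts of 0.18, 0.11 and 0.33 are computed without the list test, and with an estimated correlation they were not called. The correlation of the ubp8 null with the double null was 0.67 between different sets, and without the called, deleted and marker genes the correlations were 0.0453 (dot4 with ubp8), 0.15 (dot4 with double) and 0.11 (ubp8 with double), over the 571 ORFs left, where leaving out called genes lowers r by itself. The chromosome median farthest from 0 was 0.0383 and 0.0447 in the dot4 null with channel 1 and channel 2 alone, 0.0599 in the ubp8 null with scaling and 0.0312 with channel 1, and 0.13 in the double null with channel 2. The cause of these shifts was not tested.

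Leaving out 1 set at a time gave 3148 to 3983 called ORFs in the dot4 null, 2664 to 3780 in the ubp8 null and 3984 to 4432 in the double null. The contrasts gave 3128 to 3769, 3042 to 3711 and 2114 to 2684. The non-additive count ran from 730 (without dot4 set 3) to 1595 (without double set 3), with 803 without dot4 set 2 and 756 without ubp8 set 2. The 1.5-fold counts were 172 to 185, 27 (without ubp8 set 1) to 68 (without ubp8 set 3) and 470 to 490 in the dot4, ubp8 and double null. Lists past the threshold numbered 17 to 19, 16 to 22 and 20 to 25, and subtelomeric shifts were 0.18 to 0.20, 0.08 to 0.12 and 0.31 to 0.35. UBP10 lay between -5.21 and -4.98 in the dot4 null and between -4.75 and -4.59 in the double null, and UBP8 between -3.02 and -2.85 in the ubp8 null and between -3.09 and -2.78 in the double null. The set numbers were not taken as pairing, since the residuals of sets with the same number did not all correlate above 0.1. For sets 1 to 3 they correlated at 0.27, 0.05 and 0.15 (dot4 with ubp8), 0.09, 0.14 and 0.24 (dot4 with double) and 0.09, -0.11 and -0.26 (ubp8 with double), and with the set number as a block the counts were 3825, 3646, 4387, 3614, 3607, 2712 and 1272. Without the array with the conflicting strain number they were 4383 for the double null, 3523 and 2600 for its contrasts and 1155 for the non-additive ORFs. Distances of 10 and 30 kb were not run, since the table names no genome build. With 5 and 15 ORFs per arm the shifts were 0.31 and 0.14 in the dot4 null, 0.11 and 0.08 in the ubp8 null and 0.46 and 0.24 in the double null. How signal strength limits the ratios was not examined, since no intensities were used here.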

Other observations

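The tests of this part were chosen after the results were seen. The ORFs of Ty elements, whose copies arrays do not separate, were tallied without a list test. Of 21 Ty ORFs, 18 were called lower in the dot4 null and all 21 in the ubp8 null and the double null, with medians of -0.41, -0.46 and -0.90. The medians depended on the orientation, at -0.71 and -0.32 in the dot4 null with the null RNA in channel 1 and channel 2, -1.79 and -0.18 in the double null, and -0.96 in the ubp8 null, where the median turned to 0.07 with channel 2. Against the sum of the single nulls their median was -0.09, and 1 ORF was called.

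Of 23 iron regulon genes 12 were higher and 6 lower in the double null, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.188). The cell wall mannoprotein genes FIT3 (1.31 ± 0.13) and FIT1 (1.06 ± 0.08) rose, while the siderophore transporter gene ENB1 fell (-0.84 ± 0.03). Both the pheromone gene MF(ALPHA)1 (0.70 ± 0.05) and the receptor gene STE3 (0.69 ± 0.05) rose, and all 5 alpha-specific genes were higher with a median of 0.37 (adjusted p = 0.0323, and adjusted p = 0.249 with an estimated correlation), a call that ended with channel 2 alone (adjusted p = 0.0662). The a-specific list (3 higher and 2 lower of 8, adjusted p = 0.673) and the haploid-specific list (2 higher and 6 lower of 13, adjusted p = 0.329) were not called in this strain. CYC7, a cytochrome c gene, rose (0.72 ± 0.04), as did DAL1 of allantoin breakdown (1.17 ± 0.08) and GAL10 of galactose use (0.67 ± 0.06).

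A hypothesis for the pair of URA3 and ADH4 is that the strains carry a URA3 reporter near the end of chromosome VII, beside ADH4, which DOT4 may help to keep silent. The labels name no reporter, and a marker at the deletion itself would also change URA3. Loss of DOT4 alone would leave both genes equally high in the double null, whereas they differed from the dot4 null there by -2.26 and -1.46, so the hypothesis does not account for these values by itself. A PCR across the left end of chromosome VII in each strain would show whether a reporter lies there. It would not show whether DOT4 keeps it silent, or whether a marker also lies at the deletion.

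A difference between the 2 orientations that was specific to each ORF ran through the arrays. A dye effect cannot be told apart here from another difference between the arrays of the 2 orientations. The mean ratios of the 2 orientations correlated at 0.41 in the dot4 null, 0.45 in the ubp8 null and 0.79 in the double null, and 726, 233 and 126 ORFs were called in opposite directions by them. The rule for naming genes allowed 561 values, of which 29 turned in sign under at least 1 alternative, each time with the arrays of a single orientation.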
